A study of Homo sapiens with 13 samples.

How the data were processed

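Gene expression was measured on 13 Affymetrix U133 Plus 2.0 arrays, a 1-colour platform, in HOS osteosarcoma cells. Per the labels' protocols, cells received virus with control shRNA SHC002 or FOXR1 shRNA B4 or B8 at a multiplicity of infection of 3, total RNA was isolated with Trizol and RNeasy, and 4 µg was labelled with a One-Cycle kit after a check of its integrity. Control, B4 and B8 have 1 array each at 16, 24, 48 and 72 h, and 1 array holds cells at 0 h with no virus. Per the submitters' processing notes, signals came from MAS5 in GCOS, with versions not given in the sources used here. The deposited values are in the unit intensity, on a linear scale, scaled by the authors so that the trimmed mean of each array is 99.98 to 99.99. Array medians run from 13.3 to 16.6, the highest signals from 6959.7 to 9084.5, and 1 to 6 probe sets per array are listed at 0. The 3' to 5' signal ratios are 1.07 to 1.21 for ACTB and 0.894 to 0.991 for GAPDH. The hairpin sequences, the number of separate cultures and the days of transduction are not given in the sources used here.

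Of 54675 probe sets, 62 are controls, 41091 have 1 gene, 1801 have several and 11721 have no gene name. Of those with 1 gene, 41037 matched a gene of RefSeq GRCh38.p14, which was used for names and neighbours alone. Probe sets with several genes or no name were not analysed here. A pseudocount of 4, the 25th percentile of all values, was added before log2. The probe set with the highest mean stood for each of 19775 genes, and the upper 60% of genes by mean log2 value were kept, 11865 genes down to a mean of 4.15, which is a signal of 13.7. The number of arrays, 4 per construct, limits the precision of every estimate.

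Two-sided tests used limma 3.58.1 in R 4.3.3 with moderated variances that follow the intensity trend, and adjusted p-values follow Benjamini and Hochberg over the 11865 genes at a threshold of 0.05. The model for constructs had the factors construct and time (6 residual degrees of freedom, 11.9 with moderation) and gave the mean of B4 and B8 against control, each hairpin against control, and B4 against B8. The model for time had a slope on log2 hours for each construct (6 residual degrees of freedom, 14.6 with moderation) and gave the mean slope and the difference between the hairpins and control. All p-values measure only the spread between these arrays, since time points are not true replicates and nothing says that the arrays come from separate cultures. FOXR1 was also tested by exact permutation of the construct labels within each time. Because B4 and B8 share control arrays, genes called with both were set against 20 simulations of unchanged groups on shared control arrays and against splits of the control arrays that give each hairpin its own.

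There were 29 gene lists, of which 28 were tested and 1, haematopoietic markers, had fewer than 5 genes left and was not analysed here. The lists hold 855 measured genes. The test was camera with a correlation of 0.01, adjusted over the 28 lists within each comparison, beside camera with the correlation estimated from the data and fry. Some genes stand in more than 1 list, such as CXCL1, CXCL8 and ICAM1 among NF-kB and secretory genes and MYC among immediate early genes and MYC targets. For the single array with no virus, list medians were compared with 10000 random lists of the same size, matched on mean signal. FOXR1 is named in every comparison. Beyond it, the named genes are the 10 largest rises and 10 largest falls past the threshold that keep their direction at every time, 5 and 5 for B4 against B8 and for the trend difference, and the 4 leading members of each shifted list. Genes named among the trend differences shared by both hairpins were not chosen by such a rule, but as examples after the data were seen. For no virus they are the 10 highest and 10 lowest differences outside the range of the 12 transduced arrays, 1 of which is not reported here.

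The groups, comparisons, lists and the first set of alternatives were chosen before the data were examined. These alternatives were pseudocounts at the 10th and 50th percentile, quantile normalization, centring each array on its median, no filter and the upper 40% of genes, the mean of all probe sets of a gene, eBayes without trend, array weights, time left out as a block, 48 and 72 h alone, 16 and 24 h alone, linear hours, and each array left out in turn. Chosen after the data were seen were the trend differences of each hairpin alone with their lists, the fits without 16 h or without 72 h arrays, and the alternatives for the no virus array. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

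The steps were tested on simulated data with 67, 67 and 66 genes of 11865 changed by log2 0.5, 1 and 2. For the mean of both hairpins 49.3%, 91% and 100% were recovered with 5.9% of calls false, for B4 40.3%, 92.5% and 100% (3.7% false), for B8 38.8%, 88.1% and 100% (5% false), and for B4 against B8 40.3%, 92.5% and 100% (3.1% false). For the time trend 92.5%, 100% and 100% were recovered (5.3% false), for the trend difference 67.2%, 94% and 100% (7.9% false), and for that of B4 alone 64.2%, 83.6% and 100% (4.6% false) and of B8 alone 58.2%, 92.5% and 100% (7.7% false). A simulated list of 40 genes shifted by 0.3 was found by camera (adjusted p = 2.2e-41), and of 100 unchanged lists 0 passed. All simulated noise was independent between genes, so this does not cover lists whose genes move together. In the real data the estimated correlation reached 0.84 for ribosomal proteins.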

Results

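These data come from HOS osteosarcoma cells that received a control shRNA or 1 of 2 shRNAs against FOXR1, a forkhead transcription factor, called B4 and B8. Each of the 3 constructs was profiled on 1 array at 16, 24, 48 and 72 h, and 1 further array holds cells at 0 h with no virus. The comparisons ask how far FOXR1 transcript fell and which genes differ from control with the hairpins together and with each alone. They also ask where B4 and B8 differ, which genes move with time and whether that movement differs with FOXR1 shRNA. A last one sets untransduced cells beside control cells at 16 h.

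FOXR1 transcript was abundant in HOS cells and lower with both hairpins at every time. Its signal in control cells was 1132.6, 1043.1, 957.8 and 812.8 at 16, 24, 48 and 72 h, and 1069.4 without virus. With B4 it was 657.5, 407.1, 304.5 and 263.7, and with B8 334.6, 189.9, 181.5 and 161.8. As a percent of control at the same time this is 58.1, 39.0, 31.8 and 32.4 with B4 (mean 40.3 ± 12.3, SD, n = 4 times) and 29.5, 18.2, 18.9 and 19.9 with B8 (mean 21.7 ± 5.31). Over both hairpins FOXR1 fell by 1.78 on the log2 scale (SD 0.35 over 4 times), lower in 8 of 8 hairpin arrays (exact permutation p = 0.0123, two-sided). The exact test used all 81 arrangements of the labels within times. B4 alone gave -1.34 (SD 0.40) and B8 alone -2.21 (SD 0.32), each with an exact permutation p of 0.125, the smallest that 16 arrangements can give. FOXR1 was lower with B8 than with B4 by 0.87 log2 (SD 0.19 over 4 times).

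**Figure D1:**
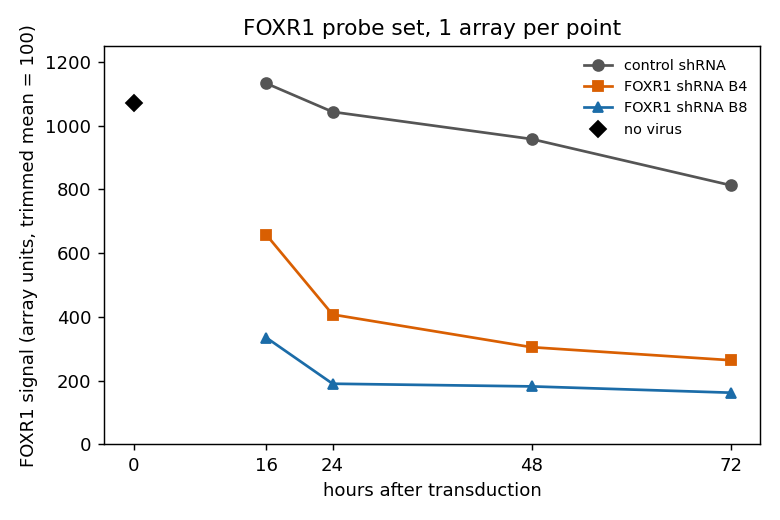
FOXR1 signal (array units, vertical axis) against hours after transduction (horizontal axis), 1 array per point, for control shRNA (circles), B4 (squares), B8 (triangles) and no virus (diamond). B4 falls from 657.5 at 16 h to 263.7 at 72 h and B8 from 334.6 to 161.8, while control goes from 1132.6 to 812.8.

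With the hairpins as 1 group (8 arrays against 4 control arrays), 87 genes differ from control, FOXR1 among them. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.82 ± 0.13 log2 (mean ± SE, adjusted p = 0.0246). Its signal was 76.7 ± 6.69 in control, 155 ± 43.3 with B4 and 127 ± 23.5 with B8 (mean ± SD, 4 arrays each). The MYC proto-oncogene rose by 0.82 ± 0.14 (adjusted p = 0.029), from a signal of 104 ± 19.9 to 226 ± 95.8 with B4 and 165 ± 43.9 with B8. TLR4, the receptor for bacterial lipopolysaccharide, rose by 1.04 ± 0.19 (adjusted p = 0.0398) and IL6R, a subunit of the interleukin 6 receptor, by 0.79 ± 0.14 (adjusted p = 0.0353). The tyrosine kinase ABL1 fell (-0.99 ± 0.18, adjusted p = 0.0336), from a signal of 279.5 ± 16.7 to 154 ± 48.3 with B4 and 140.4 ± 64.9 with B8. CCND2, a D-type cyclin, fell as well (-0.81 ± 0.16, adjusted p = 0.0448).

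The limma test covered 11865 genes and called 41 higher and 46 lower (2266 at an unadjusted p below 0.05), and 69 of the 87 moved in the same direction at every time with both hairpins. The largest rises also held PLXNC1, a semaphorin receptor (1.20 ± 0.23, adjusted p = 0.0398, but -0.28 by another probe set with the pseudocount at the 10th percentile), NUP58 of the nuclear pore (1.15 ± 0.20, adjusted p = 0.0307), and PPARA, a nuclear receptor of fatty acid metabolism (0.995 ± 0.18, adjusted p = 0.0397). CPEB2, an RNA-binding protein (0.94 ± 0.18, adjusted p = 0.0412), the kinase HIPK3 (0.83 ± 0.13, adjusted p = 0.0246) and the ciliary protein TULP3 (0.82 ± 0.13, adjusted p = 0.0246) followed. The largest falls after FOXR1 (-1.78 ± 0.11, adjusted p = 3.46e-05) were MRPL32 of the mitochondrial ribosome (-1.16 ± 0.15, adjusted p = 0.0107), SLAIN1 (-1.104 ± 0.19, adjusted p = 0.0307) and RNF141 (-1.09 ± 0.10, adjusted p = 0.0012). SMCO4 (-0.90 ± 0.11, adjusted p = 0.0086), TRIP13 of the mitotic checkpoint (-0.83 ± 0.11, adjusted p = 0.0157), DTL, a ubiquitin ligase adaptor of S phase (-0.83 ± 0.13, adjusted p = 0.0246), and C11orf96 (-0.81 ± 0.15, adjusted p = 0.0353) came next. MRPL32, RNF141 and TRIP13 passed the test with B4 and not with B8, SMCO4 and DTL with B8 and not with B4, and all 5 differ between the hairpins by a direct test. Under quantile normalization 39 genes passed (14 higher, 25 lower), and with 48 and 72 h alone 1894 did. With 1 array left out the count ran from 2 to 349. It was 349, 5, 2 and 2 without the control array at 16, 24, 48 and 72 h, 253, 24, 7 and 55 without B4, and 167, 6, 8 and 11 without B8.

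Of 28 gene lists, 12 shifted with both hairpins together by camera, 6 up and 6 down. None of the list calls in this report holds with an estimated correlation between genes. Senescence-associated secretory genes had a median log2 of 0.46 (20 genes, 16 higher in value, camera adjusted p = 8.62e-05, adjusted p = 0.578 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases and not a secreted product, is the 1 gene of the list that rose over all genes. Adjusted over the list alone, 8 rose. NF-kB and inflammatory cytokine genes had a median of 0.30 (20 of 21 higher in value, camera adjusted p = 8.62e-05, adjusted p = 0.578 with an estimated correlation). Among them, 5 rose when adjusted over the list alone, and over all genes CXCL1 stood at 1.02 ± 0.23 (adjusted p = 0.0595) and ICAM1 at 0.69 ± 0.18 (adjusted p = 0.0941). Immediate early genes had a median of 0.23 (23 of 29 higher in value, camera adjusted p = 8.62e-05, adjusted p = 0.578 with an estimated correlation). There MYC rose and the phosphatase DUSP4 fell (-0.62 ± 0.10, adjusted p = 0.0246), with 7 rises and 1 fall adjusted over the list alone. Metallothioneins (median 0.28, 10 of 10 higher in value, camera adjusted p = 0.018), the unfolded protein response (0.09, 19 of 25 higher in value, camera adjusted p = 0.013) and G2/M and mitosis genes (0.08, 36 of 45 higher in value, camera adjusted p = 0.0016) went up as lists. For each, adjusted p = 0.578 with an estimated correlation. The metallothionein shift is that of B4, since with B8 the median is -0.15 and 8 of 10 are lower in value (camera adjusted p = 0.449). Among unfolded protein response genes DNAJB9, a chaperone of the endoplasmic reticulum, rose (0.51 ± 0.10, adjusted p = 0.0398).

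Lists of DNA replication, ribosome biogenesis and oxidative phosphorylation went down. G1/S and DNA replication genes had a median of -0.15 (34 of 43 lower in value, camera adjusted p = 8.62e-05, adjusted p = 0.578 with an estimated correlation). DTL and RFC3, a clamp loader subunit (-0.95 ± 0.15, adjusted p = 0.0246), fell over all genes, and 4 fell when adjusted over the list alone. RFC3 passed with B4 and not with B8, and DTL with B8 and not with B4 (B4 minus B8 -1.82 and 0.93). MYC targets and ribosome biogenesis genes had a median of -0.15 (30 of 35 lower in value, camera adjusted p = 0.0012, adjusted p = 0.578 with an estimated correlation) while MYC itself, a member of the list, rose. ATF4 amino acid response (-0.15, 26 of 34 lower in value, camera adjusted p = 0.013), cholesterol synthesis (-0.13, 16 of 19 lower in value, camera adjusted p = 0.0152), heat shock proteins (-0.10, 14 of 20 lower in value, camera adjusted p = 0.021) and oxidative phosphorylation (-0.07, 41 of 51 lower in value, camera adjusted p = 0.0027) also went down. Each of them had adjusted p = 0.578 with an estimated correlation. The cholesterol shift is that of B8, since with B4 the median is 0.05 and 12 of 19 are higher in value (camera adjusted p = 0.543). Alone, B4 did not pass for the unfolded protein response (0.215), G2/M (0.0642) or oxidative phosphorylation (0.0769). B8 did not for G1/S (-0.04, 0.393), immediate early genes (0.183), heat shock (0.393) or ATF4 (0.128). Adjusted over the list alone, 5 heat shock genes, 1 cholesterol gene and 4 MYC target genes fell. With 16 and 24 h alone 1 list passed.

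The other 16 lists did not pass with both hairpins together. Among them, forkhead family genes had a median of -0.01 (20 genes, adjusted p = 0.603), FOXO targets 0.08 (25 genes, adjusted p = 0.217), and p53 targets -0.04 (27 genes, adjusted p = 0.988, with the test pointing up). The interferon response stood at 0.09 (30 genes, adjusted p = 0.15), hypoxia and glycolysis -0.06 (35 genes, adjusted p = 0.778) and apoptosis regulators 0.05 (30 genes, adjusted p = 0.343). Replication histones stood at 0.14 (24 genes, adjusted p = 0.0672), extracellular matrix and osteoblast genes at 0.06 (35 genes, adjusted p = 0.0684) and lysosome and autophagy genes at 0.07 (37 genes, adjusted p = 0.0706). The NRF2 oxidative stress response had a median of -0.08 (24 genes, adjusted p = 0.0533), TGF-beta and SRF/YAP targets 0.04 (26 genes, adjusted p = 0.47) and the RNA interference machinery 0.08 (15 genes, adjusted p = 0.15). Ribosomal proteins stood at -0.0029 (46 genes, adjusted p = 0.988). Markers of other cell types did not pass either: sympathoadrenal -0.07 (6 genes, adjusted p = 0.988), adipocyte and muscle 0.21 (5 genes, adjusted p = 0.15) and epithelial 0.04 (7 genes, adjusted p = 0.988).

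With B4 alone (4 arrays against 4), the largest changes were falls of genes that did not pass the test with B8, beside the fall of FOXR1 itself (-1.34 ± 0.13, adjusted p = 3.44e-04). OAZ1, the antizyme that controls polyamine synthesis, fell 5.62-fold (-2.49 ± 0.30, adjusted p = 0.0018). Its signal was 4034 ± 74.9 in control, 880.2 ± 681 with B4 and 3937 ± 250.2 with B8. MRPL32 fell 4.62-fold (-2.21 ± 0.17, adjusted p = 1.44e-04), the iron-sulfur assembly gene ISCA2 3.71-fold (-1.89 ± 0.22, adjusted p = 0.0013) and RFC3 3.61-fold (-1.85 ± 0.17, adjusted p = 2.95e-04). The ETS factor ELK3 (-1.84 ± 0.16, adjusted p = 1.59e-04), RNF141 (-1.74 ± 0.12, adjusted p = 6.65e-05) and DIPK1A (-1.59 ± 0.14, adjusted p = 1.59e-04) fell next. MDM2, the ubiquitin ligase of p53 (-1.50 ± 0.22, adjusted p = 0.0062), TCF19 (-1.48 ± 0.30, adjusted p = 0.0318) and the ribosome assembly gene RRP1 (-1.48 ± 0.17, adjusted p = 0.0013) fell too. With B8, RNF141 stood at -0.45 (adjusted p = 0.0918) and RRP1 at -0.28 (adjusted p = 0.425). Rises held RASD1, a Ras-like GTPase (1.75 ± 0.35, adjusted p = 0.0304, signal 8.73 to 46.4). Control signals of RASD1, H2BC11 (9.38) and CXCL1 (9.12) lie below 13.7, the lowest mean tested, so the pseudocount sets the size of these log2 changes (RASD1 1.21 to 2.02). The neutrophil chemokines CXCL8 (1.60 ± 0.31, adjusted p = 0.0286, signal 13.9 to 50.9) and CXCL1 (1.30 ± 0.26, adjusted p = 0.0306) rose with it. So did the histone gene H2BC11 (1.36 ± 0.30, adjusted p = 0.0426), PLXNC1 (1.33, adjusted p = 0.0304, but -0.13 by the other probe set) and ANTXR2, an anthrax toxin receptor (1.27 ± 0.28, adjusted p = 0.0413). IL6R rose by 1.03 ± 0.16 (adjusted p = 0.0089), MYC by 1.01 (adjusted p = 0.0093) and CDKN1A by 0.94 (adjusted p = 0.0082), with NUP58 (1.10), CPEB2 (1.07) and PPARA (1.06).

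B4 changed 279 genes, 94 higher and 185 lower (2500 at an unadjusted p below 0.05), and shifted 12 lists. Immediate early genes had a median of 0.43 (27 of 29 higher in value, camera adjusted p = 3.99e-07, adjusted p = 0.536 with an estimated correlation). MYC, ZFP36L1 (0.67 ± 0.14, adjusted p = 0.0327), JUN (0.71 ± 0.15, adjusted p = 0.0351) and PHLDA1 (0.89 ± 0.20, adjusted p = 0.0458) rose. DUSP4 fell (-1.04 ± 0.11, adjusted p = 7.095e-04), and 14 rose when adjusted over the list alone. The zinc-binding metallothioneins stood at 0.67 (10 of 10 higher in value, 8 past the test over the list alone, camera adjusted p = 7.51e-06) and replication histones at 0.45 (20 of 24 higher in value, 9 over the list alone, camera adjusted p = 5.83e-05). Both had adjusted p = 0.536 with an estimated correlation. Senescence-associated secretory genes (0.52, 17 of 20 higher in value, 9 over the list alone, camera adjusted p = 5.21e-06) and NF-kB genes (0.43, 18 of 21 higher in value, 3 over the list alone, camera adjusted p = 5.83e-05) had the same adjusted p = 0.536 with an estimated correlation. FOXO targets (0.18, camera adjusted p = 0.0189), matrix genes (0.14, camera adjusted p = 0.0109) and lysosome genes (0.12, camera adjusted p = 0.048) went up, each again at adjusted p = 0.536 with an estimated correlation. Among FOXO targets RICTOR (0.43, adjusted p = 0.0397) and CDKN1B (0.66, adjusted p = 0.0426) rose and BNIP3 fell (-0.89 ± 0.18, adjusted p = 0.0332). G1/S genes went down (-0.22, 38 of 43 lower in value, 10 fell over the list alone, camera adjusted p = 6.44e-08), at adjusted p = 0.536 with an estimated correlation. MYC targets (-0.13, camera adjusted p = 0.0053), heat shock proteins (-0.12, camera adjusted p = 0.0078) and the ATF4 response (-0.10, camera adjusted p = 0.0189) did so at the same adjusted p = 0.536 with an estimated correlation. RFC3, POLA2 (-0.81 ± 0.18, adjusted p = 0.0426), RRP9 (-0.57, adjusted p = 0.0415), CHORDC1 (-1.01 ± 0.19, adjusted p = 0.0255) and JDP2 (-1.28 ± 0.28, adjusted p = 0.0413) are the members that fell there. Without 1 array the count of 279 ran from 41 to 834. It was 519, 126, 43 and 57 without the control array at 16, 24, 48 and 72 h, 834, 151, 41 and 78 without B4, and with B8 arrays left out 215, 126, 95 and 252. Quantile normalization gave 183.

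With B8 alone (4 arrays against 4), FOXR1 showed the largest fall of all genes called in the same direction at every time, and 108 of the 118 genes called were not called with B4. After FOXR1 (-2.21 ± 0.13, adjusted p = 1.48e-05) came SMCO4, 3.03-fold lower (-1.60 ± 0.12, adjusted p = 7.70e-05, signal 226 in control, 74.9 with B8 and 200.2 with B4). ISCA1 of iron-sulfur assembly (-1.48 ± 0.18, adjusted p = 0.0041), GCH1 of tetrahydrobiopterin synthesis (-1.48 ± 0.23, adjusted p = 0.0156) fell next. TMF1 of the Golgi (-1.46 ± 0.20, adjusted p = 0.008) and the peroxisomal import receptor PEX5 (-1.46 ± 0.11, adjusted p = 7.70e-05, signal 136 to 46.4) fell by the same size. MLST8, a subunit of the mTOR complexes (-1.44 ± 0.18, adjusted p = 0.0051), EFS (-1.36, signal 24.7 to 8.2, near the floor), SLAIN1 (-1.34 ± 0.22, adjusted p = 0.019) and the HSP90 cochaperone FKBP4 (-1.33 ± 0.25, adjusted p = 0.0271) fell as well. Rises held NUP58 (1.20, adjusted p = 0.0288), TLR4 (1.19, adjusted p = 0.0273), CCDC148 (1.15 ± 0.22, adjusted p = 0.0288) and the secretory granule protein SCG2 (1.099 ± 0.22, adjusted p = 0.0393). The Hippo pathway kinase LATS2 (0.98 ± 0.19, adjusted p = 0.0288, signal 323 to 691), the cell cycle kinase CDK6 (0.96 ± 0.18, adjusted p = 0.0271) and TULP3 (0.93, adjusted p = 0.019) rose too. HIPK3 (0.87, adjusted p = 0.0222), ZNF367 (0.78 ± 0.14, adjusted p = 0.0249) and the cation channel TRPC4 (0.78 ± 0.15, adjusted p = 0.0301) rose less. MYC stood at 0.63 (adjusted p = 0.0827) and CDKN1A at 0.69 (adjusted p = 0.0525).

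B8 changed 118 genes, 29 higher and 89 lower (2128 at an unadjusted p below 0.05), and shifted 7 lists. Cholesterol synthesis went down (median -0.27, 18 of 19 lower in value, 9 fell over the list alone, camera adjusted p = 1.68e-06, adjusted p = 0.683 with an estimated correlation). Over all genes LSS stood at -0.40 ± 0.10 (adjusted p = 0.077), HMGCS1 at -0.44 (adjusted p = 0.0974) and SQLE at -0.51 (adjusted p = 0.102). Oxidative phosphorylation (-0.09, 45 of 51 lower in value, camera adjusted p = 0.0012, adjusted p = 0.684 with an estimated correlation) and MYC targets (-0.08, 29 of 35 lower in value, camera adjusted p = 0.0096, adjusted p = 0.683 with an estimated correlation) went down. G2/M genes (0.13, 33 of 45 higher in value, camera adjusted p = 9.58e-04), the unfolded protein response (0.15, 20 of 25, camera adjusted p = 0.0044), NF-kB genes (0.15, 15 of 21, camera adjusted p = 0.0249) and senescence-associated secretory genes (0.39, 15 of 20, camera adjusted p = 0.0347) went up. Each had adjusted p = 0.683 with an estimated correlation. Without 1 array the count of 118 ran from 8 to 434. It was 310, 63, 8 and 9 without the control array at 16, 24, 48 and 72 h, 124, 87, 65 and 218 without B4, and 434, 57, 8 and 18 without B8.

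The genes called with both hairpins are few. FBXW7, a ubiquitin ligase subunit that marks cyclin E and MYC for degradation (B4 0.52 ± 0.10, adjusted p = 0.0286, B8 0.58 ± 0.10, adjusted p = 0.0241), HIPK3, NUP58, TULP3, ARHGAP18, DENND6A, ANKRD36B and ZNF678 rose with both. FOXR1 and ABL1 fell with both (ABL1 with B4 -0.89, adjusted p = 0.0438, with B8 -1.09, adjusted p = 0.0271). These are 8 higher and 2 lower. Independent lists of these lengths would share 0.23 and 1.39 and simulated unchanged groups on the same control arrays shared 0. The simulated noise was independent between genes, and arrangements of the real array labels gave up to 67 shared genes. B4 and B8 are both measured against the same 4 control arrays, so their changes correlate across genes (r = 0.39, against 0.50 in simulated unchanged groups). With separate control arrays r is 0.0775 to 0.222. At an unadjusted p below 0.05 in both, 633 genes go the same way and 34 opposite ways, against 128 and 1.2 simulated. The count of 10 was 103, 7, 1 and 1 without the control array at 16, 24, 48 and 72 h, 15, 4, 2 and 8 without B4, and 18, 2, 1 and 1 without B8.

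**Figure D2:**
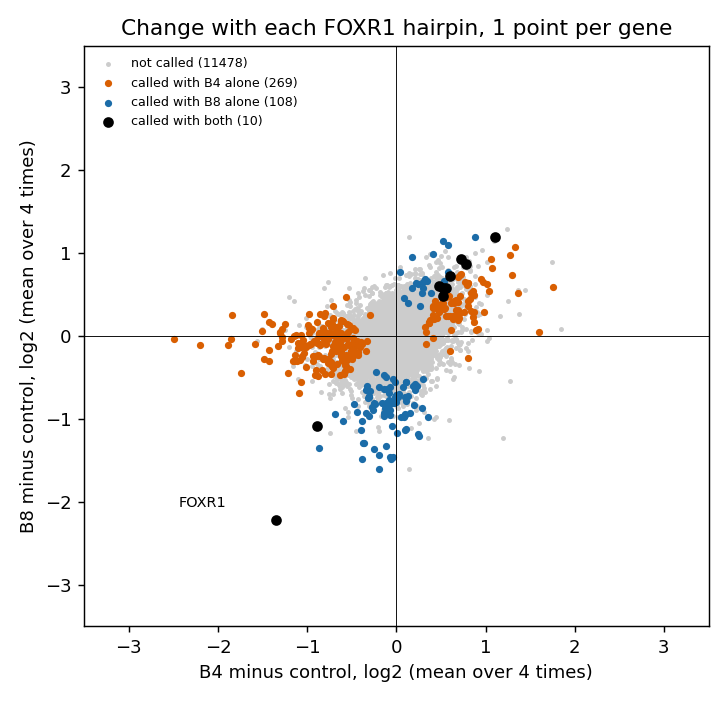
Mean log2 change over 4 times with B4 (horizontal axis) and B8 (vertical axis) against control, 1 point per gene, 11865 genes. Genes called with B4 alone (269) spread along the horizontal axis, those with B8 alone (108) along the vertical axis, and the 10 called with both, FOXR1 among them, lie off both axes.

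Compared directly (4 arrays against 4), B4 and B8 differ in 498 genes, 242 higher and 256 lower with B4 (2676 at an unadjusted p below 0.05). Higher with B4 are EGR1, an immediate early transcription factor (2.43 ± 0.60, adjusted p = 0.0456, signal 706 ± 667 with B4, 123 ± 174 with B8), the metallothionein MT1M (1.81 ± 0.45, adjusted p = 0.0451) and the cytokine IL11 (1.77 ± 0.45, adjusted p = 0.0483). The protease inhibitor TIMP2 (1.60 ± 0.35, adjusted p = 0.0266) and CD44, a hyaluronan receptor (1.59 ± 0.29, adjusted p = 0.0138, signal 1814 and 653), are higher too. Lower with B4 are OAZ1 (-2.45, adjusted p = 0.0016), MRPL32 (-2.10, adjusted p = 1.35e-04), ELK3 (-2.10, adjusted p = 1.05e-04), RFC3 (-1.82, adjusted p = 2.26e-04) and ISCA2 (-1.78, adjusted p = 0.0016). FOXR1 is higher with B4 by 0.87 ± 0.13 (adjusted p = 0.0046). Of the 279 genes called with B4, 127 also differ between the hairpins, and 74 of the 118 called with B8. Without 1 array the count of 498 was 423, 338, 326 and 473 for control at 16, 24, 48 and 72 h, 1064, 372, 85 and 180 for B4, and 896, 321, 94 and 121 for B8.

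Between the hairpins 10 lists differ, 9 higher with B4. Metallothioneins lead (median 0.87, 10 of 10 higher in value, camera adjusted p = 3.11e-06, adjusted p = 0.62 with an estimated correlation). Past the test over all genes are 4 members, MT1M, MT1G (1.20 ± 0.27, adjusted p = 0.0331), MT1E (0.997 ± 0.24, adjusted p = 0.0394) and MT1F (1.35 ± 0.34, adjusted p = 0.0465). Cholesterol synthesis genes stand at 0.31 (16 of 19 higher in value, camera adjusted p = 3.11e-06, adjusted p = 0.62 with an estimated correlation). They have 6 members past the test, among them MSMO1 (0.75 ± 0.12, adjusted p = 0.0063) and HMGCS1 (0.64 ± 0.12, adjusted p = 0.0138). Replication histones stand at 0.48 (22 of 24 higher in value, camera adjusted p = 3.11e-06, adjusted p = 0.683 with an estimated correlation). Their 3 members past the test are H2BC12 (0.9985, adjusted p = 0.0273), H2BC6 (0.99, adjusted p = 0.0233) and H2BC9 (0.96, adjusted p = 0.0336). G1/S genes are lower with B4 (-0.19, 35 of 43 lower in value, camera adjusted p = 4.54e-05, adjusted p = 0.757 with an estimated correlation). There 2 members are higher, DTL and RFC5 (0.79 ± 0.16, adjusted p = 0.0178), and 5 lower, GINS1 among them (-1.24 ± 0.28, adjusted p = 0.032). Ribosomal proteins (0.10, 45 of 46 higher in value, camera adjusted p = 2.10e-04, adjusted p = 0.807 with an estimated correlation), and immediate early genes (0.27, camera adjusted p = 5.49e-04, adjusted p = 0.757 with an estimated correlation) are higher with B4. FOXO targets (0.18, camera adjusted p = 0.0193, adjusted p = 0.683 with an estimated correlation) and senescence-associated secretory genes (0.25, camera adjusted p = 0.0361, adjusted p = 0.764 with an estimated correlation) follow. So do epithelial markers (0.13, 7 genes, camera adjusted p = 0.0363, adjusted p = 0.62 with an estimated correlation), with KRT8 at 0.86 (adjusted p = 0.031), and TGF-beta and SRF/YAP targets (0.21, camera adjusted p = 0.0391, adjusted p = 0.757 with an estimated correlation). Under quantile normalization 9 lists differ, 7 of them higher with B4.

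**Figure D3:**
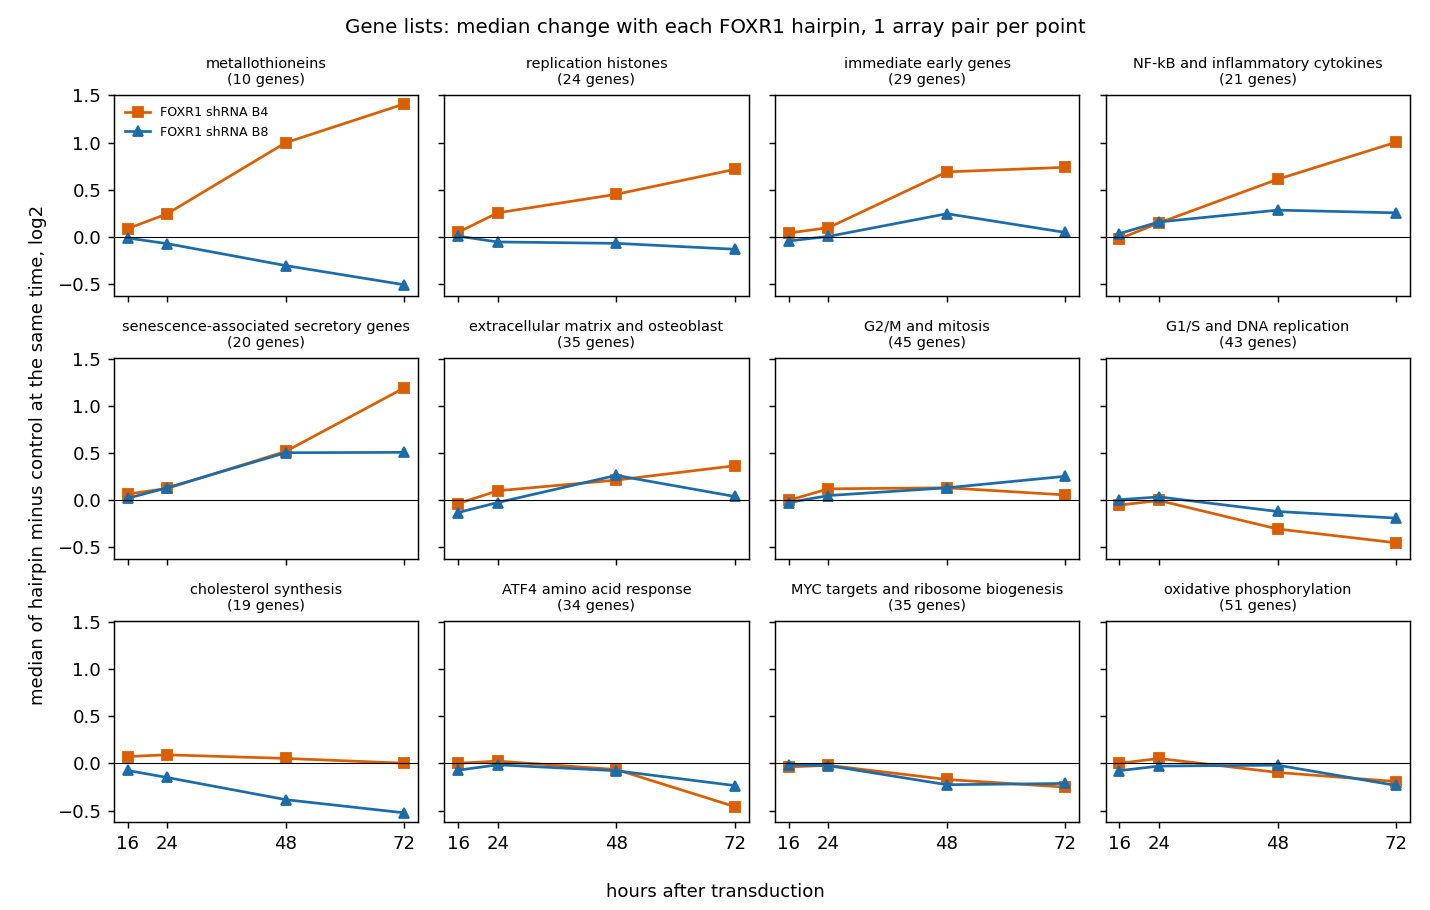
Median log2 difference to control at the same time (vertical axis) against hours after transduction (horizontal axis) for 12 gene lists, B4 as squares and B8 as triangles, 1 array pair per point. Metallothioneins reach 1.41 with B4 and -0.50 with B8 at 72 h, replication histones 0.72 and -0.13, and cholesterol synthesis 0.00 and -0.52.

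Over time, by the mean slope of the 3 constructs (12 arrays), lists of matrix and interferon genes rose and those of ribosome assembly and DNA replication fell. In control alone 11 of 35 matrix genes rose and 7 of 35 MYC targets fell, but 0 of 43 G1/S genes fell and 0 of 30 interferon genes rose. MAMDC2, a matrix-associated protein, rose by 1.15 ± 0.05 log2 per doubling of time (adjusted p = 1.45e-08). From 16 to 72 h its signal went from 182.2 to 517.5 in control, 168.7 to 789.2 with B4 and 165.5 to 1839.5 with B8. MYLIP (1.01 ± 0.12, adjusted p = 1.61e-05), HSPG2, the basement membrane proteoglycan perlecan (1.01), and the cytochrome P450 gene CYP1B1 (0.998 ± 0.10, adjusted p = 4.52e-06) rose. So did PLSCR4 (0.92), LOC90246 (0.91), PNRC1 (0.90), MGARP (0.86), the granzyme inhibitor SERPINB9 (0.83) and NTN4 (0.81). SNRNP25 of the minor spliceosome (-0.67 ± 0.05, adjusted p = 4.14e-07), FKBP4 (-0.65 ± 0.03, adjusted p = 3.24e-08), and EIF3B of translation initiation (-0.61 ± 0.03, adjusted p = 3.24e-08) fell. KLHL21 (-0.61), SRM, the spermidine synthase (-0.59 ± 0.05, adjusted p = 8.77e-07), CCDC86 (-0.59), B3GALT6 (-0.59), IMP4 (-0.58) and MICOS13 (-0.58) fell. So did the signal of an HBB probe set (-0.74 ± 0.09, adjusted p = 1.45e-05) and FOXR1 (-0.39 ± 0.05, adjusted p = 5.47e-05). EIF3B went from 2250.8 to 1886.8 in control and from 2010.2 to 211.8 with B4. The test called 5233 of 11865 genes, 2535 rising and 2698 falling (6067 at an unadjusted p below 0.05). Of the 5233, 1728 lay on the same side of their 16 h value at every later time with all 3 constructs. The test called 2848 without the 16 h arrays and 2851 without the 72 h arrays.

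With time, 13 lists shifted. MYC targets and ribosome biogenesis fell (median slope -0.21, 30 of 35 genes fell, camera adjusted p = 6.26e-12, adjusted p = 0.514 with an estimated correlation). RRP12 (-0.50) and RRP9 (-0.46) are examples beside SRM. G1/S genes (-0.18, 34 of 43 fell, camera adjusted p = 5.70e-09) such as GINS2 (-0.46, adjusted p = 4.28e-06) and MCM10 (-0.30) fell, at adjusted p = 0.514 with an estimated correlation. So did heat shock proteins (-0.21, 16 of 20 fell, camera adjusted p = 4.54e-07) such as HSF1 (-0.47) and HSPE1 (-0.36), at adjusted p = 0.514 with an estimated correlation. In control alone 2 of 20 heat shock genes fell, and the HSF1 slope was lower with the hairpins than in control (below). The heat shock median went by -0.21 from 16 to 72 h in control, -0.69 with B4 and -0.42 with B8. Ribosomal proteins (-0.09, 26 of 46 fell, camera adjusted p = 2.11e-06, adjusted p = 0.526 with an estimated correlation) and oxidative phosphorylation (-0.08, 27 of 51 fell, camera adjusted p = 1.31e-05, adjusted p = 0.514 with an estimated correlation) complete the falling lists. For these 2 lists, 0 of 46 and 1 of 51 genes fell in control alone. Interferon response genes rose (0.36, 22 of 30 rose, camera adjusted p = 1.41e-06, adjusted p = 0.514 with an estimated correlation). PSMB9 (0.78, adjusted p = 9.90e-04), SAMD9 (0.61), IFITM1 (0.56) and MX1 (0.55, adjusted p = 2.60e-04) rose. In control and with B4 the 72 h arrays stand apart here, with a median log2 signal of 6.48 (others 5.57 to 5.69) and 6.80 (others 5.63 to 5.69). Matrix and osteoblast genes rose (0.21, 22 of 35 rose, camera adjusted p = 2.21e-06, adjusted p = 0.514 with an estimated correlation). COL6A3 (0.94, adjusted p = 2.36e-05), BMP4 (0.80, adjusted p = 5.68e-07) and COL3A1 (0.48) rose. NF-kB genes (0.24, camera adjusted p = 0.0018) and immediate early genes (0.13, camera adjusted p = 0.0054) rose, both at adjusted p = 0.514 with an estimated correlation. Among the latter FOS (1.74 ± 0.33, adjusted p = 6.99e-04) and EGR1 (1.26 ± 0.26, adjusted p = 0.0013) rose. FOXO targets (0.16, camera adjusted p = 0.0087) with CCNG2 (0.78) and SESN3 (0.67), and secretory genes (0.17, camera adjusted p = 0.0188) with PLAU (0.72, adjusted p = 2.21e-07) rose at adjusted p = 0.514 with an estimated correlation. In control alone the NF-kB, secretory and immediate early medians went by -0.15, -0.14 and 0.0033 from 16 to 72 h. For immediate early genes the median went by 0.59 with B4 and 0.18 with B8. G2/M genes (0.05, 18 of 45 rose, camera adjusted p = 0.0136) and the ATF4 response (0.09, 15 of 34 rose, camera adjusted p = 0.0445) with DDIT4 (1.16) and ASNS (0.54) rose at adjusted p = 0.526 with an estimated correlation. In control alone 13 of 34 ATF4 genes and 1 of 45 G2/M genes rose. The ATF4 median went by 0.44 from 16 to 72 h in control, but by -0.04 with B4 and 0.12 with B8. By fry, which tests each list on its own, 22 lists pass, and under quantile normalization camera gives 11 rising and 3 falling.

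The mean slope of the 2 hairpins differed from that of control in 646 genes, but 22 of 81 arrangements of the construct labels within times gave as many. IL1RAP, the interleukin 1 receptor accessory protein, had a slope 1.25 ± 0.19 log2 per doubling above that of control (adjusted p = 0.0027). From 16 to 72 h its signal went from 53.9 to 23.6 in control, 42.7 to 176.1 with B4 and 42.9 to 188.0 with B8. LYPD1 (1.37 ± 0.29, adjusted p = 0.0127, control signal 11.8, near the floor), the cytokine IL24 (1.19 ± 0.18, adjusted p = 0.0025), the interferon-inducible GTPase GBP3 (1.04 ± 0.12, adjusted p = 4.95e-04) and TMEM255A (0.99 ± 0.20, adjusted p = 0.0123) also rose relative to control. IL24 went from 98 to 29.7 in control, 87.4 to 412.8 with B4 and 96.0 to 74.1 with B8. HES6 (-0.83 ± 0.17, adjusted p = 0.0109), SHISA3, an antagonist of Wnt signalling (-0.79 ± 0.12, adjusted p = 0.0027), AFMID (-0.71 ± 0.19, adjusted p = 0.0464), TATDN2 (-0.66 ± 0.09, adjusted p = 0.0017) and the nucleosome-binding HMGN5 (-0.66 ± 0.13, adjusted p = 0.0107) fell relative to control. FOXR1 itself stood at -0.28 ± 0.11 (adjusted p = 0.165). Of the 646, 358 have a higher and 288 a lower slope (2537 at an unadjusted p below 0.05).

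**Figure D4:**
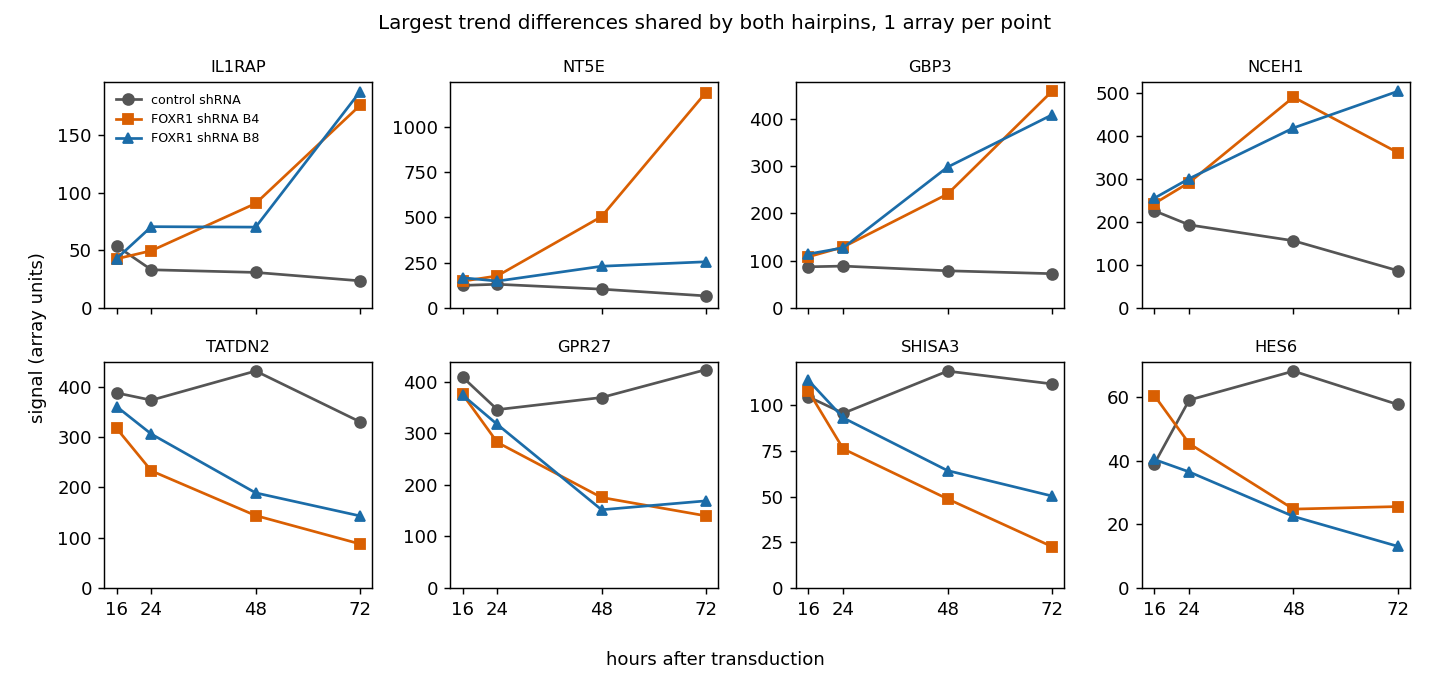
Signal (array units, vertical axes from 0) against hours after transduction (horizontal axes) for 8 genes, 1 array per point, control as circles, B4 as squares and B8 as triangles. IL1RAP ends at 176.1 and 188.0 with the hairpins against 23.6 in control, and TATDN2 at 87.6 and 143.3 against 330.5.

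By hairpin, 1031 genes have another trend with B4 and 484 with B8, 156 with both in the same direction (112 higher, 44 lower, and 10 called in opposite directions). Independent lists would share 10.0 and 10.9, and simulated unchanged groups on shared control arrays 0.05, but 8 of 100 arrangements of the labels reached 156 (highest 506). NT5E, the ecto-enzyme CD73, went from 124.3 to 66.5 in control, 147.5 to 1188 with B4 and 166.6 to 254.6 with B8 (slope differences 1.78, adjusted p = 4.102e-05, and 0.72, adjusted p = 0.0287). EGFR, the epidermal growth factor receptor, went from 412.4 to 301.9 in control, 439 to 827.5 with B4 and 405.1 to 727.5 with B8 (0.71, adjusted p = 4.116e-04, and 0.63, adjusted p = 0.00338). A second EGFR probe set agrees (364.9 to 308.5, 446.4 to 758.6 and 401.4 to 643.3), while another went from 205.9 to 154.6, 286.6 to 288 and 255.2 to 179.7, with no gain by B8 over control. The semaphorin and VEGF coreceptor NRP1, the metalloprotease ADAM12, tissue factor F3, CCND1, YAP1, DICER1 and the TGF-beta type II receptor TGFBR2 rose in the same way. Among the falls relative to control were MCM6 of the replicative helicase (1395 to 1658 in control, 1514 to 1074 with B4, 1478 to 608.1 with B8) and ABL1 (269.1 to 300.4, 212.8 to 107.8 and 205.9 to 78.0). The cholesterol genes SQLE and DHCR7, the orphan receptor GPR27 and RCC2 fell in the same way. The genes named here were picked as examples after the data were seen, not by size. The trends of B4 and B8 differ from each other in 1001 genes.

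For the trend differences 17 lists shifted, 9 up and 8 down, several with 1 hairpin alone. NF-kB genes went up (median 0.46, 17 of 21 higher in value, camera adjusted p = 8.59e-05, adjusted p = 0.388 with an estimated correlation), with IL11 (0.84 ± 0.09, adjusted p = 3.83e-04), PTX3 (0.69 ± 0.09, adjusted p = 0.0011) and IL6 (1.08 ± 0.26, adjusted p = 0.0292). Secretory genes went up (0.31, 16 of 20 higher in value, camera adjusted p = 4.79e-05, adjusted p = 0.388 with an estimated correlation), with PLAU (0.91 ± 0.10, adjusted p = 5.62e-04), PLAUR (0.76 ± 0.14, adjusted p = 0.0065) and MMP1 (1.16 ± 0.24, adjusted p = 0.0128). Matrix genes (0.14, 10 of 35 rose, camera adjusted p = 1.01e-04) with COL6A1 (0.70 ± 0.09, adjusted p = 0.0014) and LOX (0.46 ± 0.08, adjusted p = 0.005) went up at adjusted p = 0.388 with an estimated correlation. As lists that went up, immediate early genes (0.19, camera adjusted p = 7.46e-06) with DUSP5 (0.53, adjusted p = 0.0048) and FOSL1 (0.49, adjusted p = 0.0144) had adjusted p = 0.388 with an estimated correlation. Metallothioneins (0.19, camera adjusted p = 3.21e-04) with MT1X (0.40, adjusted p = 0.0088) and MT1H (0.63, adjusted p = 0.0109) had the same adjusted p = 0.388 with an estimated correlation. The unfolded protein response (0.08, camera adjusted p = 0.0166, adjusted p = 0.51 with an estimated correlation) with ATF6 (0.53, adjusted p = 0.0155) and lysosome genes (0.09, camera adjusted p = 0.008, adjusted p = 0.588 with an estimated correlation) with CTSB (0.49, adjusted p = 0.0067) went up. So did G2/M genes (0.07, camera adjusted p = 0.009, adjusted p = 0.626 with an estimated correlation) and the interferon response (0.19, camera adjusted p = 0.0156, adjusted p = 0.626 with an estimated correlation).

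By hairpin, NF-kB genes stood at 0.53 with B4 (camera adjusted p = 1.294e-06, adjusted p = 0.184 with an estimated correlation) and 0.17 with B8 (camera adjusted p = 0.19). Secretory genes stood at 0.44 with B4 (camera adjusted p = 2.113e-06, adjusted p = 0.184 with an estimated correlation) and 0.21 with B8 (camera adjusted p = 0.0951). Metallothioneins went opposite ways, 0.59 with B4 and -0.23 with B8. G2/M and unfolded protein response genes passed with B8 alone.

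G1/S genes went down against the control trend (-0.19, 37 of 43 lower in value, camera adjusted p = 2.13e-07, adjusted p = 0.439 with an estimated correlation). MCM6 (-0.54 ± 0.06, adjusted p = 4.95e-04), GINS2 (-0.54 ± 0.10, adjusted p = 0.0065) and POLA2 (-0.45 ± 0.11, adjusted p = 0.0243) are among the 7 that fell, with 16 over the list alone. MYC targets (-0.14, camera adjusted p = 2.04e-05) with SRM (-0.46, adjusted p = 0.0173) and the ATF4 response (-0.16, camera adjusted p = 3.62e-04) with SHMT2 (-0.43, adjusted p = 0.003) went down at adjusted p = 0.439 with an estimated correlation. Heat shock proteins (-0.16, camera adjusted p = 3.68e-05) with HSF1 (-0.88 ± 0.14, adjusted p = 0.0028) went down at adjusted p = 0.388 with an estimated correlation. So did cholesterol synthesis (-0.11, camera adjusted p = 6.29e-04) with DHCR7 (-0.48, adjusted p = 0.0048), and the NRF2 response (-0.08, camera adjusted p = 0.0471) with GCLM (-0.30, adjusted p = 0.0411), both at adjusted p = 0.388 with an estimated correlation. Ribosomal proteins (-0.10, 46 of 46 lower in value, camera adjusted p = 1.89e-05, adjusted p = 0.626 with an estimated correlation) and oxidative phosphorylation (-0.07, camera adjusted p = 2.36e-04, adjusted p = 0.588 with an estimated correlation) with NDUFB5 (-0.50, adjusted p = 0.0017) completed the lists. G1/S genes stood at -0.19 with B4 (13 fell, camera adjusted p = 1.458e-10, adjusted p = 0.328 with an estimated correlation) and -0.10 with B8 (2 fell, camera adjusted p = 0.036, adjusted p = 0.734 with an estimated correlation). The ATF4 and NRF2 responses passed with B4 alone. Cholesterol synthesis stood at -0.05 with B4 (camera adjusted p = 0.132) and -0.22 with B8 (camera adjusted p = 6.999e-05, adjusted p = 0.734 with an estimated correlation), but B4 against B8 did not pass (camera adjusted p = 0.0764) and DHCR7 and SQLE fell with both. The trend count of 646 was 28 without the 16 h arrays and 126 without the 72 h arrays. Without the control array at 16, 24, 48 and 72 h it was 68, 411, 460 and 91, without B4 625, 466, 759 and 525, and without B8 429, 452, 785 and 479. The 156 genes shared by both hairpins became 27, 79, 109 and 22, then 117, 106, 182 and 98, and 37, 75, 169 and 43.

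Cells with no virus, compared with control cells at 16 h (1 array each, so no test), had less cholesterol synthesis transcript. That list had a median of -0.32, at percentile 0 of 10000 random lists of its size, and HMGCS1, which makes the precursor of mevalonate, had a signal of 421.8 against 659.8 (216.9 against 274 by its second probe set). Random lists hold unrelated genes, so the percentiles here take no account of list genes that move together. Lysosome genes stood at -0.15 (percentile 0.01), oxidative phosphorylation at -0.07 (percentile 0.04), MYC targets at 0.05 (percentile 99.6), G2/M genes at 0.05 (percentile 99.9) and epithelial markers at 0.28 (percentile 99.1). All these lists kept their direction against B4 and B8 at 16 h. Yet B4 minus no virus was only -0.01 for epithelial markers, and B8 minus no virus only 0.01 for oxidative phosphorylation. The control array at 16 h also has a high 18S rRNA reading, 412 (other control arrays 57.1 to 68.5). Above the range of all 12 transduced arrays lay GALR3, a galanin receptor (33.5 against 6.4), NUTM1 (33.4 against 8.0), FAM83A (45.6 against 12.8) and HLA-F-AS1 (113.6 against 41.9). RASL11A (21.5 against 6.2), LYZL4 (27.8 against 8.8), PARTICL (37.1 against 12.6), PSG6 (26.6 against 8.5) and FLJ40288 (42.9 against 15.6) lay above it too. Below it lay the transcription factor MEF2D (4.1 against 38.5, but 6.7 with B8 at 16 h), HBB (8.9 against 51.5), STXBP2 (4.6 against 28.8), and ZNF438 (4.9 against 24.0). So did MAP3K6 (2.3 against 15.7), NYNRIN (1.6 against 13.4), LINC01208 (8.8 against 34.3), ZSCAN30 (8.2 against 32.0), MELTF-AS1 (4.9 against 18.6) and SCAND2P (4.9 against 18.5). Except for HLA-F-AS1 and FLJ40288, each gene named here has at least 1 of its 2 signals below 13.7, the lowest mean tested. RASL11A and HLA-F-AS1 only just cleared the highest transduced values, 20.1 and 103.1. FOXR1 was 1069.4 against 1132.6. In all 95 genes were 2-fold apart, 57 higher and 38 lower without virus, against 59 higher and 59 lower between B4 and control at 16 h. The 95 became 153 and 22 with a pseudocount at the 10th and the 50th percentile, and under quantile normalization the split was 50 higher and 52 lower.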

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

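In this part the arrangements of array labels for the counts fixed in advance were chosen before the results were seen, while those for each hairpin's trend and the tests of explanations for falls seen with 1 hairpin, growing differences and HBB were chosen after.

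B4 and B8 differ by a direct test in 498 genes, 10 lists and, for the time trend, 1001 genes, and their mean trend differs from control in 646 genes and 17 lists. Of the genes named with the hairpins, 29 differ between them. B4 minus B8 is 0.87 for FOXR1, and for genes that fell with B4 it is -2.10 for MRPL32, -1.29 for RNF141, -0.78 for TRIP13, -2.45 for OAZ1 and -1.78 for ISCA2. It is -1.82 for RFC3, -2.10 for ELK3, -1.49 for DIPK1A, -1.57 for MDM2, -1.75 for TCF19 and -1.21 for RRP1. For genes that fell with B8 it is 1.40 for SMCO4, 0.93 for DTL, 1.43 for ISCA1, 1.09 for GCH1, 1.43 for TMF1, 1.39 for PEX5, 1.25 for MLST8, 1.11 for EFS and 1.21 for FKBP4. For rises it is 1.54 for CXCL8, -0.79 for CDK6 and -0.73 for ZNF367. The largest differences that favour B4 are 2.43 for EGR1, 1.81 for MT1M, 1.77 for IL11, 1.60 for TIMP2 and 1.59 for CD44. Slopes above control are 1.37 for LYPD1, 1.25 for IL1RAP, 1.19 for IL24, 1.04 for GBP3 and 0.99 for TMEM255A. Slopes below are -0.83 for HES6, -0.79 for SHISA3, -0.71 for AFMID, -0.66 for TATDN2 and -0.66 for HMGN5.

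Single arrays stood far from the other 3 of their construct in 10 of 108 groups of 4, against 5.04% of simulated groups of independent values. Each group is a time course and some lists share genes, so a change with time can also make an array stand out. The excess is therefore no measure of faulty arrays. The 18S rRNA control probe read 412 at 16 h in control (others 57.1 to 68.5) and 108.2 at 16 h with B4 (others 44.3 to 53.3). Interferon response genes had a median log2 signal of 6.48 at 72 h in control (others 5.57 to 5.69) and 6.80 at 72 h with B4 (others 5.63 to 5.69). At 48 h in control, sympathoadrenal markers stood at 7.14 (others 6.79 to 6.83) and adipocyte and muscle markers at 5.05 (others 4.60 to 4.65). With B4, hypoxia and glycolysis genes stood at 8.81 at 72 h (others 8.16 to 8.24) and TGF-beta and SRF/YAP targets at 9.25 at 48 h (others 8.91). With B8, FOXR1 read 334.6 at 16 h (others 161.8 to 189.9) and oxidative phosphorylation genes stood at 10.61 at 16 h, close to the others at 10.56 to 10.57.

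For the mean of both hairpins, 3 of 81 arrangements of the construct labels within times gave as many genes as the real 87, a share under 0.05. These 3 have control (87), B4 (463, the highest other) or B8 (307) as the control at 48 and 72 h, so the count does not single out the control construct. For genes called with both hairpins, 3 of 100 arrangements reached the real 10, and the highest other gave 67. Since each construct has 1 time course, neither the 87 nor the 10 can be set apart from a chance difference between cultures. For the time trend 1 of 100 reached the real 5233 (highest other 3482), so a chance order of the times within constructs can be excluded. For B4 (real 279, highest other 0), B8 (real 118, highest other 0) and B4 against B8 (real 498, highest other 1), 1 of 8 arrangements each was as large. These 8 are too few for a share under 0.05. For the trend difference, 22 of 81 arrangements reached the real 646 (highest other 1653). For trends called with both hairpins 8 of 100 reached the real 156 (highest other 506), so chance cannot be excluded for either. All arrangements that reached 646 keep 1 construct together at 48 and 72 h: 9 of 9 with B4, 7 of 9 with B8 and 6 of 9 with control, against 0 of 54 with different constructs (highest count 1). Together with the 463 and 307 above, this points to a structure of the samples in which each construct stands apart from the others late in the course. For the trends of single hairpins, 3 of 8 arrangements were as large for B4 (real 1031, highest other 1621), 3 of 8 for B8 (real 484, highest other 1124) and 3 of 8 for B4 against B8 (real 1001, highest other 1784), again too few for a share under 0.05.

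Over the 4 times more genes fell than rose with each hairpin, 183 with B4 and not B8 and 87 with B8 and not B4, but with 48 and 72 h alone 1033 were higher and 1148 lower with B4, 793 and 842 with B8, and 556 were called with both, and without the control array at 16 h B8 gave 153 and 157. A dose effect of the lower FOXR1 with B8 would need B4 falls to be at least as deep with B8. To ask this, 184 genes were picked by their B4 fall at 2 of the times. But their B8 share at the other 2 times was at most 0.115 (highest upper quartile 0.454). For the 88 falls with B8 a dose effect cannot be told apart. Their share with B4 was 0.0939 (quartiles -0.06 to 0.29, FOXR1 itself 0.608). These genes were picked by their B8 fall on the same arrays, so a low share with B4 is partly built in. FOXR1 may also have to fall below some level first. Of the falls with 1 hairpin 10, or 3.70%, had a signal with the other hairpin within the lowest 25% of genes (upper 95% bound 6.71%), which argues against noise near the floor. Lowering by the hairpin itself, direct or off target, is a candidate explanation that cannot be told apart: falls had reached a share of 0.484 of their late size by 16 and 24 h and rises 0.452, a difference of 0.0319 (permutation p = 0.317 of 10000, two-sided). The hairpin sequences, which would allow a search for matching sites, are not given in the sources used here, and a biological difference between the hairpins' cultures was not tested.

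The differences to control grow from 16 to 72 h with both hairpins. The control's own trend accounts for at most 1.92% of the variance of the trend differences. That share cannot decide whether cells with FOXR1 shRNA only move faster along the course of control. On log2 hours, a steady gain in pace shifts a straight course and leaves its slope unchanged. Whether the control array at 16 h, with its high 18S reading, carries the growth cannot be told apart: without it 646 and 156 genes become 68 and 27, but without control at 72 h they become 91 and 22. Without all 16 h arrays 28 and 2 are left. A response to lower FOXR1 may underlie the shared part, but the structure of the samples described above leaves that open.

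An HBB probe set read 8.9 without virus, a mean of 56.4 at 16 h, and less at each later time with B4 and with B8. The other HBB probe sets rose at most 1.64-fold from no virus to 16 h, against 6.34-fold here. That 6.34-fold is uncertain, since 8.9 lies below 13.7, the lowest mean tested. The other probe sets read 4.9, 2.5 and 17.9 without virus, near the floor, so HBB mRNA from blood or HOS cells cannot be told apart. Another candidate explanation is a sequence brought in with the virus preparation and lost afterwards, since envelope plasmids for such virus can carry globin sequences: the share left at 72 h was at most 0.415 (0.261 with B4, 0.229 with B8). The plasmids are not given in the sources used here, and no other biological explanation was tested.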

How the results depend on the processing

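In this part the fits without 16 h or 72 h arrays, the trends of single hairpins and the alternatives for no virus were chosen after the data were seen, all others before. Where no cause follows from an alternative's own construction (fewer arrays or genes), the cause was not tested. FOXR1 transcript kept its direction and its side of the threshold under both pseudocounts, both scalings and each array left out (log2 -1.95 to -1.64). Across the scalings the median change of all genes lay no further from 0 than -0.0233. Of 364 pairs of a named gene and a comparison, 174 kept direction and side under every alternative and 8 reversed under at least 1. Array signal limits what can be seen: genes with a mean signal below 13.7 were not tested, and near this floor the pseudocount sets the fold.

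Below, counts are in the order both hairpins together, B4, B8, called with both, B4 against B8, time trend, trend difference, trend difference with both, with main values 87, 279, 118, 10, 498, 5233, 646 and 156. No filter gave 25, 108, 70, 4, 251, (trend within 1.5 times), 408 and 76. The mean of all probe sets gave 17, 99, 29, 2, 223, (trend within 1.5 times), 235 and 41. The fit with eBayes without trend gave 9, 91, 19, 2, 191, (trend within 1.5 times), 215 and 18. Leaving out 16 h gave 400, 796, 483, 98, 1034, 2848, 28 and 2, and leaving out 72 h gave 9, 61, 13, 1, 136, 2851, 126 and 24. For the first 5 results, 48 and 72 h alone gave 1894, 2181, 1635, 556 and 2253, and 16 and 24 h alone gave 19, 84, 39, 1 and 187. For these, no replicate block, which leaves harvest time out, gave 1, 52, 23, 1 and 169. Quantile normalization moved both hairpins together to 39 and B4 to 183, and array weights moved both together to 156, B8 to 184 and called with both to 24. The trend difference of 646 was 1031 with B4 alone, 1001 for B4 against B8 and 156 with both hairpins. The 95 genes of no virus against control became 153 with a pseudocount at the 10th percentile and 22 at the 50th. Counts under median centring, the upper 40% of genes and linear hours stayed within 1.5 times.

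With each of 12 arrays left out, counts ran from 2 (without control at 48 or 72 h) to 349 (without control at 16 h) for both hairpins together. They ran from 41 to 834 for B4 (both without a B4 array, 48 and 16 h). For B8 they ran from 8 (without B8 or control at 48 h) to 434 (without B8 at 16 h). For genes called with both they ran from 1 to 103 (highest without control at 16 h). For the rest they ran from 85 to 1064 for B4 against B8 (without B4 at 48 and 16 h), 3767 to 5428 for the time trend, 68 (without control at 16 h) to 785 for the trend difference and 22 (without control at 72 h) to 182 for those with both.

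Shifted lists numbered 12, 12, 7, 10, 13 and 17 for both together, B4, B8, B4 against B8, time trend and trend difference. With the correlation estimated from the data camera gave 0, 0, 0, 0, 0 and 0 (0, 0, 1, 1, 0 and 2 at an unadjusted p below 0.05), and fry gave 0, 0, 0, 1, 22 and 0 (4, 7, 4, 7, 22 and 11 unadjusted). With 16 and 24 h alone the first 3 became 1, 4 and 3, where heat shock proteins for both together turned to 0.0415 and the ATF4 response for B4 to 0.0155.

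Gene values that reversed were PLXNC1 with the pseudocount at the 10th percentile (-0.28 for both together, -0.13 for B4, where another probe set then stands for the gene), ME1 in the trend difference with the mean of all probe sets (0.11) and RPLP2 in B4 against B8 with array weights (-0.0675). Without single arrays RPLP2 ran from -0.12 to 0.56, with negative values without B8 at 48 h or B4 or B8 at 16 h. Trend differences turned without control at 72 h and ran from -0.27 to 0.58 for SGO1, -0.0467 to 1.31 for RELB, -1.14 to 0.11 for CHAC1 and -0.83 to 0.0068 for ASNS. Other gene calls were lost in 82 pairs with eBayes without trend, 79 with the mean of all probe sets, 55 with no filter, 22 with quantile normalization, 11 with array weights and 560 of the fits without 1 array, which gained 92.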

Other observations

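In this part the trend lists of single hairpins, the neighbours of FOXR1 and the PAFAH1B2 and HMGCS1 probe sets were chosen after results were seen.

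Metallothioneins and replication histones move apart over time with the 2 hairpins. The median metallothionein difference to control at 16, 24, 48 and 72 h was 0.09, 0.25, 0.9995 and 1.41 with B4 and -0.01, -0.07, -0.30 and -0.50 with B8. For the trend of B4 against B8, 8 of 10 genes rose (median 0.79, camera adjusted p = 6.557e-13, adjusted p = 0.105 with an estimated correlation). Replication histones, 0.05, 0.26, 0.45 and 0.72 with B4 and 0.01, -0.05, -0.07 and -0.13 with B8, had 7 of 24 genes past the same test (median 0.46, camera adjusted p = 1.161e-09, adjusted p = 0.146 with an estimated correlation). Against control, 8 metallothioneins rose in trend with B4 and 3 fell with B8. In all 14 lists shifted in the trend of B4, 13 in that of B8 and 12 between them, none of which holds with an estimated correlation.

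Cholesterol synthesis genes differ between the single 0 h array and later ones, where virus and time cannot be separated, and between the hairpins. From no virus to 16 h their median difference was 0.40 with B4 and 0.26 with B8, and control at 72 h stood 0.73 above no virus. HMGCS1 read 659.8, 704.1, 733.5 and 859.9 at 16, 24, 48 and 72 h in control, 682.2, 799.9, 970.5 and 970.1 with B4, and 552.6, 624.6, 505.8 and 498.1 with B8, against 421.8 without virus. Its second probe set read 274, 357.1, 503.5 and 409.8 in control, 569.5, 582.5, 636.9 and 533.7 with B4, and 441.3, 336, 308 and 197.4 with B8, so above control with B8 at 16 h. The interferon response list gained 0.44 from 16 to 72 h in control and 1.03 with each hairpin, while NF-kB genes gained 1.31 with B4 and 0.26 with B8, against -0.15 in control.

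Next to FOXR1 on the same chromosome, in the order DDX6, CXCR5, BCL9L, UPK2, FOXR1, CENATAC, RPS25, TRAPPC4 and SLC37A4, TRAPPC4, a subunit of a vesicle tethering complex, fell with both hairpins together (-0.55, adjusted p = 0.0398) and with B4 (-0.63, adjusted p = 0.0243), and stood at -0.47 with B8 (adjusted p = 0.0812). Its trend differed from control (-0.35, adjusted p = 0.00488), as did that of SLC37A4 (-0.40, adjusted p = 0.014), and the other neighbours did not pass, with CXCR5 and UPK2 below the signal filter. A PAFAH1B2 probe set read 1319, 1362, 1409 and 1350.0 in control at 16, 24, 48 and 72 h, 1286, 1445, 1488 and 1408 with B4, and 880.5, 802, 589.4 and 541 with B8.

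Arrays spread apart with time. The SD over genes of the log2 difference to control was 0.286, 0.298, 0.433 and 0.581 with B4 and 0.282, 0.288, 0.422 and 0.493 with B8 at 16, 24, 48 and 72 h, against 0.453 between control at 72 and 16 h and 0.28 between no virus and control at 16 h. The first 3 principal components hold 38.4%, 20.1% and 12.1% of the variance.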
